A study of Arabidopsis thaliana with 12 samples.

How the data were processed

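Total RNA from roots of Arabidopsis thaliana seedlings was labelled with biotin and hybridised to one-colour arrays with 22810 probe sets, per the labels. The authors deposited 1 log2 value per probe set and array, made with RMA (robust multi-array average, which corrects background, equalises the distribution over arrays and combines the probes of a set) in the affy package, per the submitters' processing notes. The versions of these tools, and whether the 12 arrays went through RMA together, are not given in the sources used here. RMA forces arrays processed together to similar distributions, so a change shared by most transcripts would not be seen, and it compresses differences near the background. Median log2 values per array lay between 6.07 and 6.17. Signal over background is not given per probe set, so no probe set was set aside as undetected.

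The 12 arrays fall into 4 groups of 3 by genotype and treatment, taken from the sample titles. The labels call the replicates biological, each a pool of 120 seedlings held in a single well. The ATP dose reads 100 mM in the titles and 100 µM in the treatment protocol. The designs, tests, alternatives and gene lists were fixed before the data were examined, except where stated.

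The 64 control probe sets were left out, and 22746 were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, empirical Bayes moderation without trend or robust settings, and Benjamini-Hochberg adjustment within each of 5 contrasts at an adjusted p of 0.05. The contrasts were ATP against buffer in the wild type and in dorn1-1, the difference between these responses, and dorn1-1 against the wild type in buffer and in ATP. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Comparisons of a single value per array used two-sided exact permutation tests, which cannot go below 0.1 for 3 arrays against 3.

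Gene names came from the platform annotation, which lists 14016 probe sets, 13513 with exactly 1 gene and 503 with several, and 8730 tested probe sets are not listed there and stay unnamed. Of the 1-gene probe sets, 13436 matched the RefSeq gene table of the TAIR10.1 assembly, covering 13286 genes. That table was used for names and for the chromosome of a gene only. Related genes can share probes, so members of a family may not be separated fully. The lectin receptor kinase gene mutated in dorn1-1 was not analysed here.

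Named genes were chosen by a rule set in advance, among probe sets with exactly 1 gene that passed and whose 3 arrays of one group lay on one side of the 3 of the other. The largest changes were taken, up to 15 up and 10 down for the wild-type response, 10 in each direction for the dorn1-1 response, the difference in response (without the rule on sides) and the buffer comparison, and 5 in each direction for the ATP comparison. For each gene list the members with the lowest adjusted p were named too. A gene with several probe sets is given by the one with the highest mean.

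Of 25 lists with 406 member genes, 54 members were measured on named probe sets, and 10 lists had at least 3. Every list had under 80% of its members measured (at most 40% for calcium sensing), so a list result covers the measured members only. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 10 lists of a contrast, and beside it with an estimated correlation and with fry. The mean of the 3 measured photosynthesis genes per array served as a measure of shoot tissue, since roots were cut from whole seedlings.

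The alternatives were quantile, median and cyclic loess scaling of the deposited values, a filter at the 40th percentile of mean log2 value, moderation with trend and robust settings, array weights, the replicate number as a block, a 2-fold minimum, fits of only the 2 groups compared, omission of probe sets that can bind several genes, and omission of each array in turn. Added after the data were seen were the photosynthesis mean as a covariate, this covariate without dorn1-1 buffer replicate 1, tests of 28 gene families defined by the letters that open the symbol, and a count of calls per chromosome.

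The fit was tested on simulated data with 200 changed probe sets among 22746, with noise drawn independently for each probe set and array. The real arrays also held differences shared by many probe sets, so the rates below need not hold for them. For the wild-type response it recovered 11.9% of changes of 1.41-fold, 83.6% of 2-fold and 97.0% of 4-fold, with 8 wrong among 136 calls. For the difference in response it recovered 2.99%, 58.2% and 98.5%, with 5 wrong among 111 calls.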

Results

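Root transcripts of Arabidopsis thaliana were measured on 12 one-colour arrays, in 4 groups of 3 biological replicates. The wild type was the Col-0 accession carrying aequorin, a protein that reports cytosolic calcium. The mutant, dorn1-1, has a lesion in a lectin receptor kinase that binds ATP outside the cell. Each replicate was a pool of 120 seedlings, 5 days old, held in the dark overnight in buffer with 2 mM MES and 10 mM CaCl2, and roots were taken 30 min after ATP or buffer was given. The sample titles give the ATP dose as 100 mM and the treatment protocol as 100 µM, so the dose is not settled here. After control probe sets were set aside, 22746 probe sets were tested, and the median log2 value of an array lay between 6.07 and 6.17. The number of arrays limits the precision, and a name was given only where a probe set lists exactly 1 gene.

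The first comparison asked which root transcripts differed 30 min after ATP in the wild type. CML40 (AT3G01830), a calmodulin-like calcium sensor, rose 4.83-fold, from a log2 value of 5.04 ± 0.09 in buffer to 7.31 ± 0.46 in ATP (SD, n = 3 each, limma adjusted p = 0.0164). AT3G02840, an armadillo-repeat gene of a family induced early by fungal elicitors, rose 4.27-fold, from 5.74 ± 0.04 to 7.83 ± 0.13 (SD, n = 3 each, limma adjusted p = 3.94e-05). AT5G52760, which encodes a heavy-metal-associated domain protein, rose 3.58-fold, from 4.19 ± 0.17 to 6.04 ± 0.09 (SD, n = 3 each, limma adjusted p = 6.83e-05). AT5G05300 and AT3G10930, both of which encode small peptides, rose 3.09-fold (log2 change 1.63, SE 0.23) and 2.95-fold (log2 change 1.56, SE 0.17). AT5G18470, a curculin-like lectin gene, rose 3.03-fold, and AT1G28600, a GDSL-type lipase gene, rose 3.04-fold, with SEs of 0.21 and 0.32 on the log2 scale. AT3G44630, of the TIR-type resistance gene class, rose 2.59-fold, and AT2G42360, a RING-type ubiquitin ligase gene, rose 2.58-fold, with log2 SEs of 0.26 and 0.27. The other 6 genes named among the risers were AT1G19380, AT5G19240, AT3G54150, AT1G56060, AT2G37540 and AT1G55450, with log2 changes of 1.71, 1.57, 1.46, 1.40, 1.39 and 1.36.

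Fewer transcripts fell in the wild type. AT4G30170, a peroxidase gene, fell 2.31-fold, from 10.19 ± 0.16 to 8.98 ± 0.20 (SD, n = 3 each, limma adjusted p = 0.00649). AT2G37870, of the lipid transfer protein type, fell 2.26-fold (log2 change -1.18, SE 0.18), AT2G28710, a C2H2 zinc finger gene, fell 1.98-fold (log2 change -0.99, SE 0.20), and BZIP61 (AT3G58120), a basic leucine zipper factor, fell 1.97-fold (log2 change -0.98, SE 0.18). AT2G34610, AT2G20515, AT5G02550, AT4G29690, AT1G10900 and AT5G54370 had log2 changes between -1.25 and -0.90. In total 151 probe sets passed an adjusted p of 0.05 in limma, 109 higher and 42 lower in ATP, and 54 of the 151 differed at least 2-fold. Of the 151, 85 list exactly 1 gene, 64 are not listed in the platform annotation used here and 2 list several genes. The count was 259 with cyclic loess scaling, 228 with trend and robust moderation, 2506 with only the 2 groups in the fit and 6203 with array weights. It was 44, 6 and 10 without wild-type buffer replicates 1, 2 and 3, 85 and 18 without wild-type ATP replicates 1 and 3, 2316, 359 and 89 without dorn1-1 buffer replicates 1, 2 and 3, and 100 without dorn1-1 ATP replicate 3. Of the 25 named genes, AT3G02840, AT5G52760 and AT3G10930 passed in each of the 12 fits that left out 1 array, and the other 22 missed the threshold in at least 1, with the highest adjusted p of 0.232 for AT2G28710 without wild-type ATP replicate 3.

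**Figure D1:**
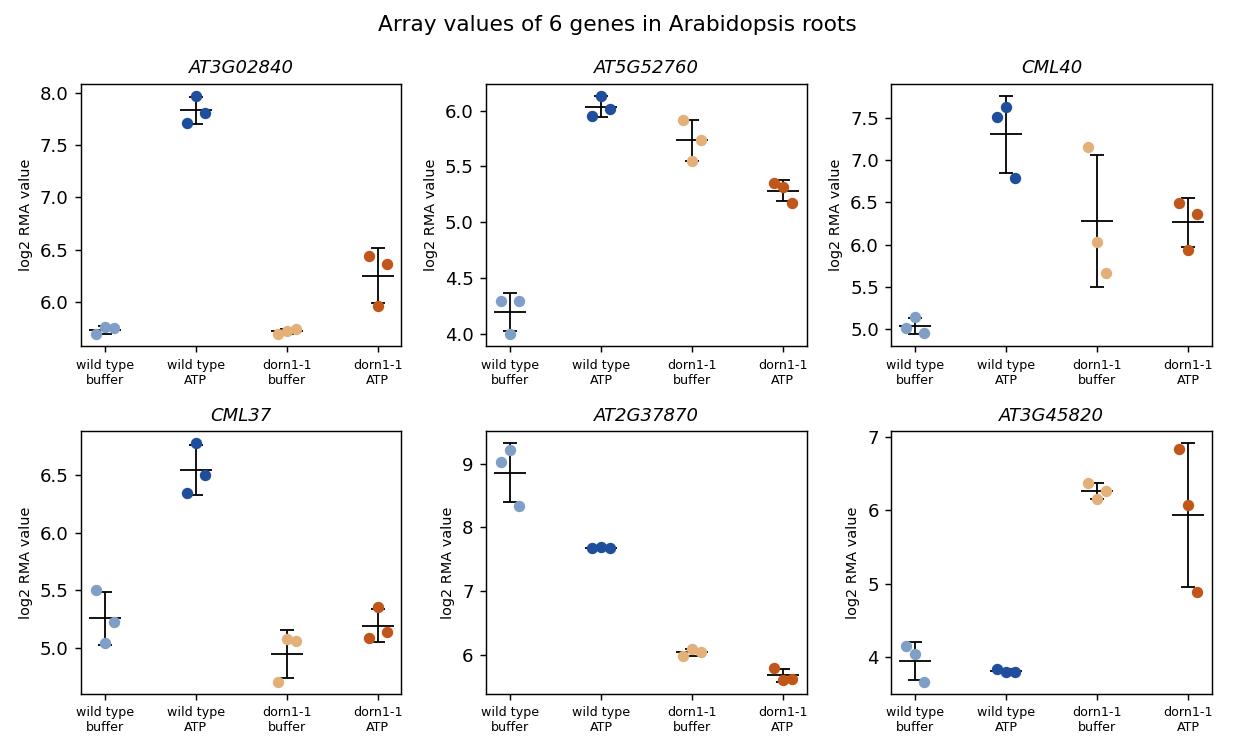
Log2 values (y axis) of AT3G02840, AT5G52760, CML40, CML37, AT2G37870 and AT3G45820 on each of the 12 arrays, by group (x axis), with points for arrays and bars for the mean ± SD of 3 arrays. AT3G02840 stood at 7.83 in the wild type with ATP and at 6.25 in dorn1-1 with ATP, against 5.74 and 5.72 in buffer.

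Gene lists fixed before the data were examined were tested as groups. The calcium sensing list rose with ATP in the wild type, with a median log2 change of 0.30 and a higher mean in ATP for each of its 10 measured members. CML40 and CML37 passed over all probe sets, CML37 with a 2.44-fold rise from 5.26 ± 0.23 to 6.54 ± 0.22 (SD, n = 3 each, limma adjusted p = 0.00785). Adjusted over the list alone, 4 members passed, these 2 and the calmodulin-like genes CML45 (log2 change 1.30, SE 0.31) and CML23 (log2 change 0.69, SE 0.21). The list had a camera adjusted p = 1.05e-05, and adjusted p = 0.106 with an estimated correlation. The pattern-triggered immunity list also rose, with a median log2 change of 0.38, a camera adjusted p = 0.0139, and adjusted p = 0.114 with an estimated correlation. By limma 0 of its 5 members passed over all probe sets and 3 had an unadjusted p under 0.05. Adjusted over the list alone, 2 passed, PUB22, a U-box ubiquitin ligase (log2 change 0.38, SE 0.11), and BIK1, a kinase that acts with immune receptors (log2 change 0.50, SE 0.18). The oxidative stress list fell, with a median log2 change of -0.79, a camera adjusted p = 0.0283, and adjusted p = 0.307 with an estimated correlation. By limma 0 of its 3 members passed over all probe sets, 2 had an unadjusted p under 0.05, and the same number passed adjusted over the list alone, the glutathione transferase genes GSTU22 (log2 change -0.91, SE 0.20) and GSTU25 (log2 change -0.79, SE 0.28). The wider family of 11 measured GSTU genes, tested after the data were seen, did not pass. Its median was -0.25, and 6 of the 11 were lower (camera adjusted p = 0.750).

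Transcripts of green tissue moved with these groups. The photosynthesis list (RCA, LHCB4.1 and PRK), fixed as a marker of shoot tissue, rose in the wild type with a median log2 change of 1.08, a camera adjusted p = 0.0283, and adjusted p = 0.336 with an estimated correlation. By limma 0 of its 3 members passed over all probe sets, 1 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone, PRK (phosphoribulokinase, log2 change 1.94, SE 0.58). The mean of the 3 genes was 10.30 ± 0.47 in wild-type buffer, 11.64 ± 0.49 in wild-type ATP and 10.47 ± 1.40 in dorn1-1 buffer (SD, n = 3 each), and the 3 dorn1-1 ATP arrays lay between 10.63 and 11.27 (SD 0.33). The wild-type difference of 1.34 had an exact permutation p of 0.1, two-sided, the smallest that 3 arrays against 3 allow. The mean of 69 plastid-encoded probe sets differed by 0.65 in the same direction in the wild type, also with an exact permutation p of 0.1. In dorn1-1 buffer, replicate 1 stood at 11.89 and replicate 2 at 9.09. Across the 12 arrays the photosynthesis mean followed the plastid-encoded mean (Pearson r = 0.94, Spearman rho = 0.95) and the first principal component (r = 0.94, rho = 0.92), which held 47.8% of the variance. Each Pearson permutation p was 1e-05, the smallest that 100000 resamples can give, and stayed at 1e-05 after Benjamini-Hochberg adjustment over the 2 relations. The Spearman permutation p was 1e-05 and 8e-05, or 2e-05 and 8e-05 adjusted. Without the 2 arrays farthest from the median, r was 0.91 in both, and within groups, after each group mean was removed, it was 0.92 and 0.95. The GAPDH control probe sets, a sign of RNA integrity, had a 3' minus 5' log2 difference of -0.25 ± 0.10 in wild-type buffer and -0.60 ± 0.07 in wild-type ATP (SD, n = 3 each, exact permutation p = 0.1). The actin control probe sets, read the same way, gave 3.54 ± 0.19 and 3.26 ± 0.17 (SD, n = 3 each, difference -0.29, exact permutation p = 0.2). With the photosynthesis mean as a covariate, an alternative added after the data were seen, 78 probe sets passed, 74 higher and 4 lower, and 53 of the 151 were among them. In that fit 10 of the 25 named genes passed, among them AT3G02840 (log2 change 2.09), AT5G52760 (1.75), CML40 (1.84) and AT4G30170 (-1.07).

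**Figure D2:**
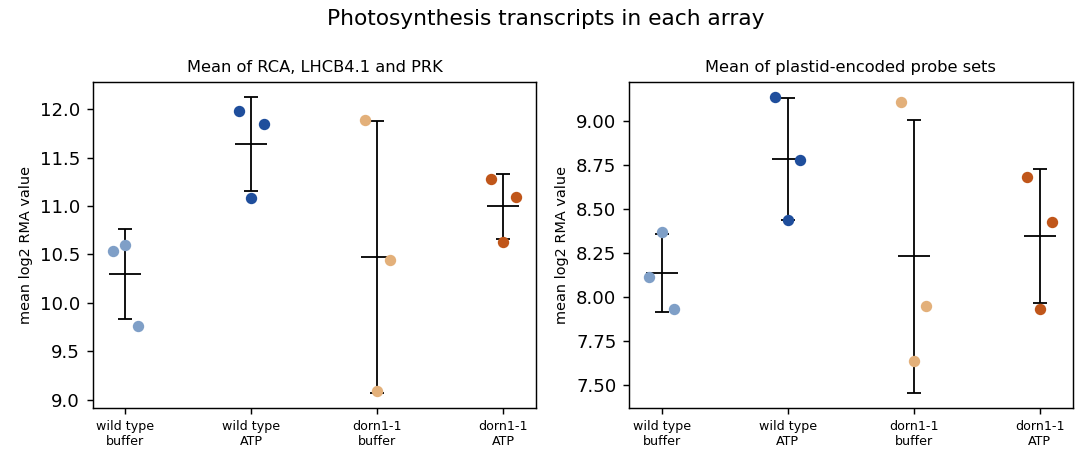
Mean log2 value (y axis) of RCA, LHCB4.1 and PRK and of the plastid-encoded probe sets on each of the 12 arrays, by group (x axis), with points for arrays and bars for the mean ± SD of 3 arrays. Buffer arrays of dorn1-1 spread from 9.09 to 11.89 in the photosynthesis mean.

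The remaining lists with at least 3 measured members did not pass camera in the wild type. The zinc finger, NAC and MYB list had an adjusted p = 0.407, with ZAT10, a zinc finger repressor named STZ in the annotation, at a log2 change of 0.90 (SE 0.19), past the threshold only adjusted over the list alone; its median of -0.06 and mean of 0.21 differed in sign. The touch and cell wall list had an adjusted p = 0.0794, with XTH18, a xyloglucan endotransglucosylase, at a log2 change of 0.82 (SE 0.18), likewise past the threshold only adjusted over the list alone. The WRKY list had an adjusted p = 0.215, the auxin list 0.842, and the abscisic acid and reference gene lists 0.912 each. By limma 0 members of these 4 lists passed over all probe sets or adjusted over the list alone, and the abscisic acid list held 1 member with an unadjusted p under 0.05, COR47 (log2 change -0.37, SE 0.13).

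The same treatment was compared in the mutant. AT3G02840 had log2 values of 5.72 ± 0.02 in dorn1-1 buffer and 6.25 ± 0.26 in dorn1-1 ATP (SD, n = 3 each). The difference was 0.53 (SE 0.13, limma adjusted p of 1.00). No probe set had a lower adjusted p in dorn1-1, so this value does not separate large from small changes. CML40 stood at 6.28 ± 0.78 and 6.27 ± 0.29, and CML37 at 4.95 ± 0.21 and 5.19 ± 0.14 (SD, n = 3 each). AT5G52760 stood at 5.74 ± 0.18 in buffer and 5.28 ± 0.09 in ATP (SD, n = 3 each), both above the wild-type buffer level of 4.19. By limma 0 probe sets passed in dorn1-1, and 523 had an unadjusted p under 0.05, where about 1137 would by chance. None of the 10 gene lists tested passed, with the lowest camera adjusted p of 0.288 for calcium sensing. Without dorn1-1 buffer replicate 1, the array with the high photosynthesis mean, 12 probe sets passed. Across all 22746 probe sets the wild-type and dorn1-1 changes correlated with r = 0.50 (rho = 0.38), which is across genes, and genes are not independent replicates. The photosynthesis mean was also higher with ATP in both genotypes, by 1.34 and 0.52 (exact permutation p = 0.1 and 0.6). A shared response and a shared shift in shoot tissue were not told apart here.

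The difference between the ATP responses of the genotypes was tested directly, as the dorn1-1 change minus the wild-type change. AT5G52760 differed by -2.30 on the log2 scale (SE 0.18, limma adjusted p = 0.000556): its log2 change with ATP was 1.84 in the wild type and -0.45 in dorn1-1, from buffer levels of 4.19 and 5.74. AT3G02840 differed by -1.56 (SE 0.18, limma adjusted p = 0.0215), with changes of 2.09 in the wild type and 0.53 in dorn1-1. These were the 2 probe sets that passed, both lower, and 1585 had an unadjusted p under 0.05. A filter on dim probe sets removed AT5G52760, and 1 passed in that fit, AT3G02840 (limma adjusted p = 0.0369). With the photosynthesis covariate 4 passed, and with array weights 6. The calcium sensing list fell in this contrast, with a median of -0.25, a camera adjusted p = 0.000396, and adjusted p = 0.178 with an estimated correlation. With the photosynthesis covariate its median was -0.079 (camera adjusted p = 0.00104). By limma 0 of its 10 members passed over all probe sets, 4 had an unadjusted p under 0.05, and 2 passed adjusted over the list alone, CML37 (-1.04, SE 0.22) and CML40 (-2.29, SE 0.47). The oxidative stress list was higher in this contrast, with a median of 0.94, a camera adjusted p = 0.00251, and adjusted p = 0.178 with an estimated correlation. By limma 0 of its 3 members passed over all probe sets, 2 had an unadjusted p under 0.05, and GSTU22 (0.94, SE 0.28) and GSTU25 (1.21, SE 0.39) passed adjusted over the list alone. The 11 measured GSTU genes, tested as a family after the data were seen, did not pass (median 0.30, 4 lower, camera adjusted p = 0.789). ZAT10 (-0.95, SE 0.27) and XTH18 (-0.98, SE 0.26) also passed adjusted over the list alone, in lists with camera adjusted p = 0.156 and 0.0547. RCA, LHCB4.1 and PRK had a median difference of -0.65 in the same contrast (camera adjusted p = 0.126). Neither the pattern-triggered immunity list (median -0.26, camera adjusted p = 0.0547) nor the WRKY list (median -0.41, camera adjusted p = 0.232) passed in it. AT5G52760 passed in each of the 12 fits that left out 1 array. AT3G02840 missed the threshold in 9 of the 12, those without any 1 of the 6 wild-type arrays, dorn1-1 buffer replicates 2 or 3, or dorn1-1 ATP replicate 3, with the highest adjusted p of 0.118 without dorn1-1 buffer replicate 3, and the count in these fits was 1.

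The probe sets called in the wild type were then followed in dorn1-1. The 109 that rose had a median log2 change of 0.95 in the wild type, where they were chosen, and of 0.10 in dorn1-1 (quartiles 0.02 and 0.22), and 84 of them were higher with ATP in the mutant. The 42 that fell had medians of -0.75 in the wild type and -0.15 in dorn1-1 (quartiles -0.30 and -0.01), and 34 of them were lower with ATP in the mutant. By limma 5 risers and 10 fallers had an unadjusted p under 0.05 in dorn1-1 in the wild-type direction, and 1 riser and 0 fallers in the opposite one. Over all 22746 probe sets 523 did in either direction. The same SEs entered the wild-type calls, so a low p is easier to reach in these probe sets. Relative to wild-type buffer, the mean of the risers was 1.00, 1.13 and 1.10 on the wild-type ATP arrays, 0.12, -0.01 and -0.02 on the dorn1-1 buffer arrays, and 0.19, 0.02 and 0.25 on the dorn1-1 ATP arrays. That of the fallers was -0.73, -0.72 and -0.92 on the wild-type ATP arrays. On the dorn1-1 buffer arrays it was already -0.38, -0.13 and -0.21, and on the dorn1-1 ATP arrays -0.46, -0.33 and -0.44. With the photosynthesis mean as a covariate, the wild-type medians of the same probe sets were 0.89 and -0.64. When the wild-type calls were made again without 1 array, the dorn1-1 median of the risers ranged from 0.0153 without dorn1-1 ATP replicate 3 to 0.47 without dorn1-1 buffer replicate 1, against 0.87 in the wild type over the 1247 risers of the latter fit. That of the fallers ranged from -0.36 without wild-type buffer replicate 3, where 3 fallers were called, to -0.0145 without dorn1-1 buffer replicate 2, where 143 were.

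**Figure D3:**
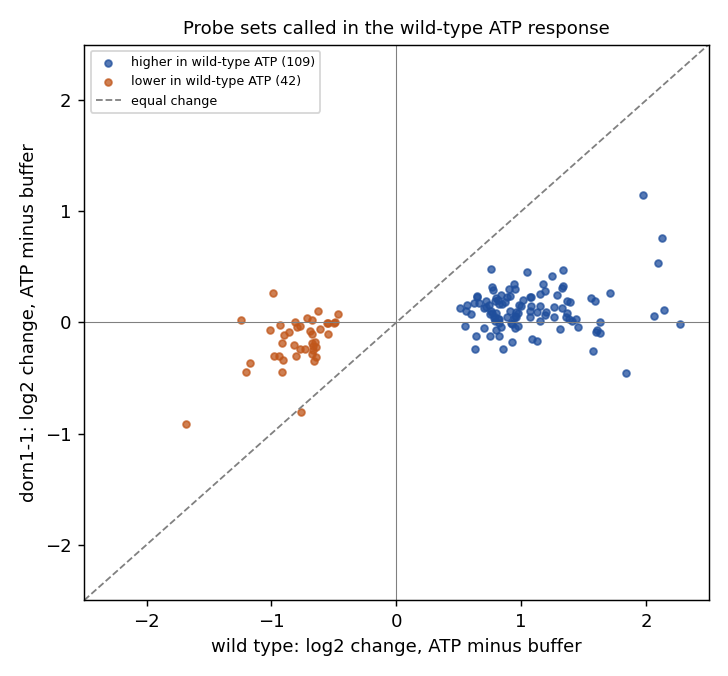
Log2 change with ATP in the wild type (x axis) and in dorn1-1 (y axis) of the 151 probe sets called in the wild type, with 1 point per probe set and a dashed line where both changes are equal. The 109 risers had medians of 0.95 in the wild type and 0.10 in dorn1-1.

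The genotypes were next compared in buffer alone. AT2G37870, of the lipid transfer protein type, was 7.05-fold lower in dorn1-1, at 6.04 ± 0.05 against 8.86 ± 0.46 in the wild type (SD, n = 3 each, limma adjusted p = 6.08e-05). OCT1 (AT1G73220), an organic cation and carnitine transporter, was 4.30-fold lower (log2 difference -2.11, SE 0.27). The cell wall genes AT2G43890, a pectin lyase-like gene, and AT1G05310, a pectin methylesterase gene, were 3.23-fold and 1.87-fold lower (log2 differences -1.69, SE 0.25, and -0.91, SE 0.12). AT5G52760 was 2.91-fold higher in dorn1-1 (log2 difference 1.54, SE 0.13, limma adjusted p = 0.000494), and AT3G45820 was 4.98-fold higher, at 6.27 ± 0.11 against 3.95 ± 0.26 (SD, n = 3 each, limma adjusted p = 0.0474). AT1G22330 and AT1G65370, a TRAF-like gene, were 1.20 and 1.19 higher on the log2 scale, and AT2G41810, AT2G02680, AT2G16660 and AT2G02630 had log2 differences of -2.22, -1.14, -1.06 and -0.95. In total 15 probe sets passed limma, 6 higher and 9 lower in dorn1-1, against 5 higher and 12 lower after each array was centred on its median. None of the gene lists passed, with the lowest camera adjusted p of 0.0897 for pattern-triggered immunity (median log2 difference -0.32). Adjusted over the list alone, 1 calcium list member, CML40 (log2 difference 1.25, SE 0.33), and 1 immunity list member, PUB23 (-0.54, SE 0.17), passed. The photosynthesis means of the groups differed by 0.18 (exact permutation p = 1), and the GAPDH 3' minus 5' log2 difference was -0.60 ± 0.29 in dorn1-1 against -0.25 ± 0.10 (SD, n = 3 each, difference -0.34, exact permutation p = 0.2), while the actin difference was higher in dorn1-1, by 0.17 (exact permutation p = 0.2). A filter on dim probe sets kept 7 of the 12 named genes, and 6 of these passed. The count was 1 with only the 2 groups in the fit, where 11 of the 12 named genes missed the threshold (highest adjusted p = 0.238), 28 with cyclic loess scaling, 8 with the filter on dim probe sets, 306 with the photosynthesis covariate and 2568 with array weights. It was 2 and 3 without wild-type buffer replicates 1 and 2, 26 and 7 without wild-type ATP replicates 2 and 3, 315, 5 and 4 without dorn1-1 buffer replicates 1, 2 and 3, and 9 without dorn1-1 ATP replicate 2. AT5G52760 and AT2G37870 passed in each of the 12 fits that left out 1 array, and the other 10 named genes missed the threshold in at least 1, with the highest adjusted p of 0.211 for AT2G02680 without wild-type buffer replicate 2.

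The genotypes were also compared with ATP present. CML45 (AT5G39670), a calmodulin-like gene, was 4.39-fold lower in dorn1-1, at 5.94 ± 0.61 against 8.07 ± 0.23 in the wild type (SD, n = 3 each, limma adjusted p = 0.00555). AT1G66090, of the TIR-NBS resistance gene class, was 4.28-fold lower (log2 difference -2.10, SE 0.50), and AT1G78450, AT2G37870 and AT2G41810 had log2 differences of -2.15, -2.01 and -1.90. The dirigent-type genes AT4G11210 and AT4G11190 were 3.49-fold and 2.95-fold higher in dorn1-1 (log2 differences 1.80, SE 0.38, and 1.56, SE 0.36). AT4G22460, of the lipid transfer protein type, was 3.55-fold higher (log2 difference 1.83, SE 0.32), and AT3G45820 and AT4G14695 were 2.12 and 1.65 higher on the log2 scale. In total 1519 probe sets passed limma, 1065 higher (70.1%) and 454 lower in dorn1-1, and 236 differed at least 2-fold. With cyclic loess scaling 57.9% of the calls were higher, 867 against 630 lower. The count was 3067 with array weights, 579 and 272 without wild-type ATP replicates 2 and 3, 2643 without dorn1-1 buffer replicate 1, and 354 without dorn1-1 ATP replicate 2. Of the 10 named genes, 5 passed in each of the 12 fits that left out 1 array, AT3G45820, AT4G14695, CML45, AT2G37870 and AT2G41810. AT1G78450 missed it in 6 of the 12, AT1G66090 in 5, AT4G11190 in 5 and AT4G11210 in 4, with the highest adjusted p of 0.171, 0.129, 0.117 and 0.0886, each without dorn1-1 ATP replicate 2, and AT4G22460 missed it in 1, without wild-type ATP replicate 3 (0.0510).

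Of the probe sets called between genotypes in buffer, 3 of the 6 higher ones and 4 of the 9 lower ones were also called in ATP in the same direction, where independent lists would share 0.281 and 0.180. The group means of the buffer and ATP comparisons share no arrays, but both comparisons take their SEs from the same fit over all arrays. A probe set with a low SE can therefore pass more easily in both. The values of 0.281 and 0.180 leave this out, so they do not show how much overlap to expect here. Counted by sign alone, 5 of the 6 higher and 9 of the 9 lower probe sets had the same direction in ATP.

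In ATP, 4 gene lists differed between genotypes. The calcium sensing list was lower in dorn1-1, with a median log2 difference of -0.34, a camera adjusted p = 0.000469, and adjusted p = 0.138 with an estimated correlation. Of its 10 members, CML37 (2.54-fold lower, log2 difference -1.35, SE 0.16) and CML45 passed over all probe sets, and 5 passed adjusted over the list alone, all lower, with CML40, CML47 and CML23 at -1.04, -0.46 and -0.67. The pattern-triggered immunity list was lower, with a median of -0.51, a camera adjusted p = 0.000469, and adjusted p = 0.0631 with an estimated correlation. This list did not pass in the difference between the ATP responses (camera adjusted p = 0.0547), and its median in buffer was -0.32. Of its 5 members, the U-box ligase genes PUB23 (log2 difference -0.90, SE 0.17) and PUB22 (-0.40, SE 0.11) passed over all probe sets, and 4 passed adjusted over the list alone. The WRKY list was lower, with a median of -0.66, a camera adjusted p = 0.0454, adjusted p = 0.257 with an estimated correlation and 0.118 with the photosynthesis covariate, where the median was -0.29. By limma 0 of its 3 members passed over all probe sets, 2 had an unadjusted p under 0.05, and WRKY22 (-0.66, SE 0.22), a defence-related transcription factor, passed adjusted over the list alone. The oxidative stress list was higher, with a median of 0.76, a camera adjusted p = 0.00255, and adjusted p = 0.171 with an estimated correlation. Its 3 members passed both over all probe sets and adjusted over the list alone, GSTU25 (2.38-fold), GSTU22 (1.70-fold) and UPOX (1.64-fold), a mitochondrial protein gene induced by oxidative stress. The 11 measured GSTU genes, tested as a family after the data were seen, did not pass (median 0.23, 5 lower, camera adjusted p = 0.604). ZAT10 (-0.90, SE 0.19, limma adjusted p = 0.0172) and XTH18 (-0.71, SE 0.18, limma adjusted p = 0.0384) also passed, although their lists did not (camera adjusted p = 0.387 each). Adjusted over the list alone, 3 members of the touch and cell wall list passed, XTH18 and XTH19 (-0.63, SE 0.21) lower and XTH20 (0.63, SE 0.18) higher in dorn1-1. The photosynthesis mean differed by -0.64 between these groups (exact permutation p = 0.3), and the GAPDH and actin 3' minus 5' values by -0.08 and 0.36 (exact permutation p = 0.6 and 0.2).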

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

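All tests of explanations here were chosen after the results were seen, except that the share of calls on chromosome 2 with the photosynthesis covariate was named before that share was computed.

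Tests of the difference between the 2 ATP responses singled out AT5G52760 (log2 difference -2.30), AT3G02840 (-1.56), the calcium sensing list (median -0.25, or -0.079 with the photosynthesis covariate) and the oxidative stress list (median 0.94, or 0.77 with it), each list with an adjusted p = 0.178 with an estimated correlation and 0.127 by fry. For the count of 2 probe sets, 4 of 100 regroupings of the 12 arrays, the real one included, gave as many calls and the highest other gave 4351, which points to a structure of the samples, but regrouping puts the genotype and treatment differences into the spread within groups (median residual SD 0.207 over the others, 0.180 in the real one), so the share does not say whether chance is excluded. The risers' mean on the dorn1-1 buffer arrays reached at most 0.122 above wild-type buffer, against 1.08 on wild-type ATP arrays. That argues against a response of wild-type size on an array labelled dorn1-1 buffer. Exchanged labels of dorn1-1 buffer replicate 1 and ATP replicate 2 would put the risers' mean at 0.19, 0.12 and 0.25 in ATP. In buffer it would be 0.02, -0.01 and -0.02. As labelled, the 2 dorn1-1 groups overlap in this mean, so a swap stays open. Without dorn1-1 buffer replicate 1 the same 109 risers had a dorn1-1 median of 0.128 against 0.954 in the wild type, which argues against that array hiding a response of wild-type size in them, but 1247 risers called again without it had medians of 0.47 and 0.87, and 14 called with the photosynthesis covariate as well had 0.35 and 1.77, so outside the 109 this stays open. Whether ATP failed to reach the mutant roots cannot be told apart from a lost response, since the risers differed by 0.12 between dorn1-1 ATP and buffer with an exact permutation p of 0.2 and 3 arrays against 3 cannot go below 0.1, and the genotype, which the design names, also stays open, with loss of the receptor not tested as a cause.

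The wild-type ATP response came with more transcripts of green tissue. With the photosynthesis mean as a covariate, the median of the 109 risers was 0.887 against 0.954 without it. That of the 42 fallers was -0.643 against -0.747. Probe sets that followed the photosynthesis mean within groups would have had high SEs and were unlikely to be called. The medians of the called ones were thus likely to hold, and do not say whether shoot tissue was a cause. The calls of all but 50 risers and 3 fallers ended. Median SEs were 0.159 before and 0.179 after for the risers, and 0.130 and 0.160 for the fallers. Of the 151, 53 passed in that fit, and 65, 80 or 61 with only the estimates, the SEs or the p cutoff taken from the fit without the covariate, so none of these alone accounts for the lost calls. The covariate's slope rests on the spread within groups, which was largest in dorn1-1 buffer (SD 1.40, against 0.33 to 0.49 in the others). The medians with the covariate hold only as far as that slope applies to the wild type. With the covariate and without dorn1-1 buffer replicate 1, 21 of the 25 named genes missed the threshold. Under 3 other scalings at least 136 of the 151 calls passed again. These were applied to RMA values with similar array medians, so they do not test the scaling within RMA. The real split gave 151 calls and the highest of the other 9 splits gave 0, but 1 of 10 is too few splits for a share under 0.05. A response to ATP, shoot tissue and RNA integrity stay open. The GAPDH and actin measures of RNA integrity differed by -0.34 and -0.29 (exact permutation p = 0.1 and 0.2) and were not tested as a cause.

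In buffer the genotypes differed in 15 probe sets, and 6 of the 12 genes named there lie on chromosome 2 against 16.4% of measured genes (Fisher's exact adjusted p = 0.0365 over 5 chromosomes). With the photosynthesis covariate 26 of 169 calls lay there, 15.4% (exact 95% interval 10.3% to 21.7%), which argues against a differing chromosome 2 segment as the source of most differences, but not for those 6 genes. The median size of the 15 changes was 1.28 with the covariate and 1.25 without it. The photosynthesis means of the 2 groups differed by only 0.18, so the covariate could move a change only a little. This result therefore does not test unequal shoot tissue, which stays open. The real split gave 15 calls and the highest other 0, with 1 of 10 splits, too few for a share under 0.05. Other mutations of the mutagenised line, the receptor lesion and RNA integrity, whose GAPDH and actin measures differed in opposite directions, by -0.34 and 0.17 (exact permutation p = 0.2 each), were not separated.

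In dorn1-1 all 10 splits gave at least the real count of 0, which any split must, so this shows nothing. Between dorn1-1 buffer replicate 1 with ATP replicates 1 and 3 and the other 3 arrays 1871 passed. This split follows the order of the photosynthesis mean and points to a structure of the samples. Exchanged labels of dorn1-1 buffer replicate 1 and ATP replicate 2 would give the same grouping. Its median residual SD was 0.164, against 0.180 for the labelled grouping, so such an exchange was not told apart from that structure. Between genotypes in ATP 1 of 10 splits reached the real count of 1519 and the highest other gave 0, too few splits for a share under 0.05.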

How the results depend on the processing

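The photosynthesis covariate, alone and without dorn1-1 buffer replicate 1, was added after the data were seen, and all other settings were planned. The wild-type count of 151 became 259 with cyclic loess, 228 with trend and robust moderation, 6203 with array weights, 54 at 2-fold, 2506 with only the 2 groups, 78 with the covariate and 14 with it and without that array, and 6 (without wild-type buffer replicate 2) to 2316 (without dorn1-1 buffer replicate 1) on leaving out 1 array. The dorn1-1 count of 0 ranged from 0 to 12 (without dorn1-1 buffer replicate 1) and was 0 in limma under every other setting, with 201 to 3154 unadjusted p under 0.05. The difference in response gave 1 with the filter on dim probe sets, 6 with array weights, 4 with the covariate, and 1 to 3 without 1 array. The buffer count of 15 became 28 with cyclic loess, 8 with the filter, 2568 with array weights, 306 with the covariate, 82 with it and without dorn1-1 buffer replicate 1, 1 with only the 2 groups, and 2 (without wild-type buffer replicate 1) to 315 (without dorn1-1 buffer replicate 1). The ATP count of 1519 became 3067 with array weights, 236 at 2-fold, and 272 (without wild-type ATP replicate 3) to 2643 (without dorn1-1 buffer replicate 1). Array weights were 0.261 for dorn1-1 buffer replicate 1 and 3.87 for replicate 3. The dorn1-1 median of the risers was 0.35 with the covariate and without that array, and 0.0153 (without dorn1-1 ATP replicate 3) to 0.47 (without dorn1-1 buffer replicate 1) without 1 array; the median of the fallers was -0.36 at 2-fold and -0.36 (without wild-type buffer replicate 3) to -0.0145 (without dorn1-1 buffer replicate 2), with no fallers left to give a value without wild-type buffer replicate 2 or in the covariate fit without that array. With the replicate number as a block the counts were 447, 0, 1, 24 and 1719 in the order above, AT3G02840 missed the threshold for the difference (adjusted p = 0.104), and no list call changed. Whether same-numbered arrays shared a batch was not settled, since the sample titles give only the number. Of 18 correlations of same-numbered arrays 8 were above 0.1, from -0.28 to 0.56, and 12 of 36 comparisons were best with their own number. Between dorn1-1 buffer and ATP the correlations were 0.48, 0.56 and 0.04 for replicates 1, 2 and 3. Of the 10 list calls, all were lost with an estimated correlation, 5 with fry, and 1 of 9 with the covariate, where the photosynthesis list is the covariate itself and was not tested; taking all probe sets of a gene moved no p of the 50 list tests and so shows nothing. No gene chosen by the naming rule turned its sign, nor did the 9 list calls tested with the covariate. Some lists without a call did, such as the auxin list in the wild type (median -0.07, and 0.11 with the covariate). For the zinc finger, NAC and MYB list in the wild type the median turned (-0.06 and 0.05), but the camera direction was up in both fits. Fewer probe sets tested, a stricter threshold or fewer arrays made some counts smaller by construction, and for the rest the cause was not tested.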

Other observations

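The tests of gene families and chromosomes were chosen after the results were seen, and covered 28 families in each of 5 contrasts.

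The UGT genes, which encode glycosyltransferases that attach sugars to small molecules, were lower in dorn1-1 than in the wild type in buffer. Of 47 measured members 37 had a lower mean, with a median log2 difference of -0.15 (camera adjusted p = 0.0133, and adjusted p = 0.478 with an estimated correlation). UGT72E2, UGT73B1 and UGT76E2 had log2 differences of -0.81 (SE 0.19), -0.68 (SE 0.15) and -0.68 (SE 0.19), and by limma 0 members passed over all probe sets, with the lowest adjusted p of 0.115 for UGT73B1, and 9 had an unadjusted p under 0.05. In ATP 30 of the 47 were lower (camera adjusted p = 0.173). With the photosynthesis covariate the buffer test had an adjusted p = 0.00822, and adjusted p = 0.888 with an estimated correlation. The GAPDH and actin 3' minus 5' values differed by -0.34 and 0.17 between these groups (exact permutation p = 0.2 each).

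The NET genes, which encode actin-binding proteins, were lower with ATP in dorn1-1. Of 10 measured members 8 had a lower mean, with a median log2 change of -0.16 (camera adjusted p = 0.0326, adjusted p = 0.624 with an estimated correlation, and 0.135 with the photosynthesis covariate), and by limma 0 passed over all probe sets and 0 had an unadjusted p under 0.05. NET2D and NET1A had log2 changes of -0.34 (SE 0.25) and -0.28 (SE 0.23). In the wild type 7 of the 10 were lower with ATP, with a median of -0.20 (camera adjusted p = 0.750), and the test of the difference between the responses had an adjusted p = 0.727.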
